A study of Arabidopsis thaliana with 10 samples.

How the data were processed

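Rosettes of Arabidopsis thaliana were profiled on single-colour oligonucleotide arrays hybridised with biotin-labelled cRNA. Per the labels' protocols, plants grew on compost at 8 h of light per day, 60% relative humidity, 23 °C by day and 18 °C by night, and 200 µmol m-2 s-1 of light. Whole rosettes were taken at 42 days and frozen, and total RNA was extracted with a column kit. The 10 arrays fall into 3 genotypes by the labels: wild type Col 0 (3 arrays), abi4-102 (3 arrays) and vtc1 (4 arrays). The titles call the samples biological replicates. The labels do not say whether a replicate is 1 plant or a pool, and p-values measure the spread between these samples.

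The values used were the authors' deposited table of linear intensity per probe set, with 22810 probe sets. How the authors summarised the probes and scaled the arrays is not given in the sources used here. The median intensity was 42.6 to 45.6 on the 10 arrays. The 64 control probe sets were set aside, leaving 22746 probe sets. Intensities were converted to log2(value + 1), so fold changes are on that scale and understate the change of dim probe sets. No further normalization was applied in the main setting.

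Gene names came from the platform annotation table, updated through a gene table of the TAIR10.1 assembly. That gene table also gave the gene type (such as pseudogene), chromosome, gene length and gene order. Of the probe sets tested, 13513 carried 1 gene, 503 carried several and 8730 were unnamed in the table used here. The 13513 probe sets covered 13355 genes, and 13436 of them matched the gene table. For 11933 of them the only symbol is the locus code. No gene was named from a probe set with several genes. A gene with several probe sets was represented by the one with the highest mean over all arrays. VTC1 and ABI4, the genes the mutants are named for, had no probe set of their own in the table used here, so their transcripts were not analysed here and the genotype labels were not checked through them.

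All 10 arrays entered 1 linear model per probe set with genotype as the only factor (limma 3.58.1 in R 4.3.3, lmFit and eBayes, moderated tests, both sides). Contrasts were drawn from it: vtc1 minus wild type, abi4-102 minus wild type, and vtc1 minus abi4-102. P-values were adjusted by Benjamini-Hochberg over 22746 probe sets, and a probe set was called at an adjusted p under 0.05 with no fold threshold. Replicate numbers were not used as a block in the main model. Tables were prepared and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Where a probe set lay below the highest of 27 Bacillus control probe sets on every array of the dimmer group, the change is given as at least N-fold. That bound sets the brighter group against the control level.

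The model was tested on simulated data with the measured spread. In vtc1 versus wild type it recovered 49% of 200 probe sets changed by 0.25 on the log2 scale and 100% of 200 changed by 0.5. In abi4-102 versus wild type it recovered 36% and 99.5%, and in vtc1 versus abi4-102 44% and 100%. False calls were at most 0.14% of the unchanged probe sets in each comparison. In each simulation 22146 of 22746 probe sets were left unchanged, whereas 36.6% of the real probe sets were called in vtc1. The adjusted threshold depends on the share changed, so neither the recovery nor the false-call rate carries over to the real counts. The number of arrays limits the precision.

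The rule for named genes was fixed before the data were examined, as were 27 gene lists with 475 listed genes. For each mutant against wild type, the rule takes the 10 largest increases and the 10 largest decreases among 1-gene probe sets that were called and whose arrays did not overlap. It takes 5 each way for vtc1 against abi4-102, and 5 each way for the overlap of both mutants, ranked by the smaller of the 2 changes. From each list it takes up to 4 called members with the largest change, or 2 members as values where none was called. VTC1 and ABI4 were to be named in any case. Only 76 listed genes had a probe set of their own, 15 lists had at least 3, and 5 lists had none: camalexin synthesis, phosphate starvation, flower markers, seed markers and epidermis markers. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists within a comparison. Below, a list is said to pass or not by camera alone. Fry, a test of a shift in one direction, gave adjusted p under 0.05 for several lists that did not pass. Examples are oxidative stress (fry adjusted p = 1.2e-06) and photosynthesis (0.00067) in vtc1, and circadian in abi4-102 (4.3e-05). For others it did not, such as flavonoid and anthocyanin synthesis in vtc1 (0.34). Fry also has a mixed test, of changes in either direction within a list. Groups of genes by symbol stem, with at least 6 measured members, and the plastid-encoded genes were formed after the data were seen.

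The alternatives tried were subtraction of array medians, quantile normalization, a filter at the 40th percentile of mean level, eBayes with trend and robust, only the 2 groups compared, array weights, a replicate block, leaving out each array, other thresholds and log2(value + 16). Scaling on the 18 hybridization spike-in probe sets, log2 without a pseudocount, and the pseudocount of 16 for results other than the vtc1 count were added after the data were seen, as was the subtraction of the median log2 change of 20 bins by gene length. Because both mutants share the wild-type arrays, 100 sets of unchanged mutants were simulated against the same controls.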

Results

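Transcript levels were measured in rosettes of wild-type Col 0 (n = 3 arrays) and of 2 mutants, vtc1 (n = 4), which is defective in ascorbate synthesis, and abi4-102 (n = 3), a mutant of an abscisic acid response transcription factor. The transcripts of VTC1 and ABI4 themselves were not analysed here, because neither gene had a probe set of its own in the annotation used. Intensity per array had a median of 42.6 to 45.6. Replicates correlated at 0.997 to 0.999 over 22746 probe sets, and arrays of different genotypes at 0.985 to 0.990. The median SD between replicates was 0.080 on the log2 scale in wild type, 0.088 in abi4-102 and 0.078 in vtc1. The first principal component carried 49.8% of the variance and placed abi4-102 between wild type and vtc1, while the second carried 32.2% and separated abi4-102 from both. Control probe sets outside the model also differed by genotype. The hybridization spike-in probe sets averaged 8.58 ± 0.13 (log2, SD, n = 4) on vtc1 arrays, 8.82 ± 0.05 (n = 3) in wild type and 8.78 ± 0.04 (n = 3) in abi4-102. The actin, GAPDH and ubiquitin controls averaged 10.97 ± 0.04, 10.58 ± 0.05 and 10.62 ± 0.01 in the same order. The 3' minus 5' log2 difference of the actin control, a sign of RNA integrity, was 1.83 ± 0.23 in wild type (n = 3), 1.48 ± 0.11 in abi4-102 (n = 3) and 1.57 ± 0.07 in vtc1 (n = 4), with every wild-type array above every mutant array. That of GAPDH was 0.40 ± 0.08, 0.29 ± 0.21 and 0.27 ± 0.10, with overlapping arrays. Scaling on the spike-in probe sets moved the median log2 change of all probe sets to 0.21 in vtc1 versus wild type and to 0.18 in vtc1 versus abi4-102. Changes of vtc1 are therefore relative to the bulk of the transcripts on the array.

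The comparison of vtc1 with wild type asks how the rosette transcriptome of the vtc1 line differs from that of Col 0. Ascorbate was not measured here, so its part in these changes was not tested. The largest increase was in AT4G12490, which rose 8.74-fold from an intensity of 88.8 ± 4.00 (SD, n = 3) to 783 ± 33.3 (n = 4; limma adjusted p = 2.0e-14). WRKY53, a transcription factor linked to senescence and defence, rose 5.14-fold from 31.6 ± 2.09 to 166 ± 8.39. LUP5 rose 5.61-fold, the kinase-like gene AT1G35710 5.13-fold, AT2G18690 4.87-fold, AT3G01830 4.79-fold and MSRB9, a methionine sulfoxide reductase, 4.65-fold. AT3G10930, AT1G26390 and the annotated pseudogene AT3G48650 were at control level in wild type and rose at least 5.18-fold, 4.64-fold and 4.70-fold. The largest decrease was in AT1G50290, which was 10.9-fold lower at 59.2 ± 4.6 against 657 ± 88.2. AT2G15560 was 8.49-fold lower, CYTC6A, a cytochrome c6-like protein of the thylakoid, 7.50-fold, AT5G15360 7.11-fold, CSLA01 6.21-fold, ACLA-2, a subunit of ATP-citrate lyase, 5.58-fold, AT1G78450 4.15-fold and AT1G31690 4.09-fold. For AT1G31690 another probe set gave a smaller change, a log2 change of -0.84. AT3G28320 and the kinase WNK9 fell to control level, by at least 5.91-fold and 4.89-fold.

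Measured genes of the endoplasmic reticulum stress and salicylic acid lists, 3 of 14 and 4 of 32 listed, rose in vtc1. All 3 measured members of the endoplasmic reticulum stress list rose: the co-chaperone ATERDJ3B 2.72-fold to 1236 ± 36.4, the calreticulin CRT1b 2.2-fold to 1537 ± 48.5, and BZIP60, a transcription factor of the unfolded protein response, 2.14-fold to 763 ± 31.1. The list mean was 1.23 (camera adjusted p = 9.9e-06, and adjusted p = 0.017 with an estimated correlation). All 4 measured members of the salicylic acid list rose, with WRKY53, the glutaredoxin GRX480 (2.07-fold), SAG101 (1.72-fold) and UGT76B1 (1.19-fold), and the list passed (adjusted p = 3.4e-05, and adjusted p = 0.017 with an estimated correlation). UGT76B1 was not called without wild type replicate 3 (log2 change 0.18) or after subtraction of array medians (0.20). Both senescence genes measured rose, SAG29 1.75-fold and WRKY6 1.59-fold, as did the zinc finger gene STZ of the oxidative stress list (3.09-fold). The other 2 members of that list were not called and the list did not pass (adjusted p = 0.22), although it did under spike-in scaling (adjusted p = 0.021). In the heat shock list 1 of 3 members rose, AT5G48570, at least 1.75-fold above control level, and the list did not pass (adjusted p = 0.28), although it did under spike-in scaling (adjusted p = 0.024).

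Members of the abscisic acid and circadian lists fell in vtc1, but only 4 of 29 and 3 of 19 listed genes were measured. RAB18 and RD29A of the first list, and CCA1 and LHY of the second, had no probe set of their own. The falls therefore do not speak for the abscisic acid response or the clock as a whole. In the abscisic acid list 3 of 4 members fell, the dehydrin COR47 from 3599 ± 21.7 to 1751 ± 22.7 (2.06-fold), COR15B 1.45-fold and COR15A 1.43-fold. All 4 fell when adjusted over the list alone, and the list passed (adjusted p = 0.0021, and adjusted p = 0.037 with an estimated correlation). In the circadian list AT4G33980 fell 3.26-fold, COR27 2.97-fold and GI 1.19-fold, with a list mean of -1.17 (adjusted p = 0.00068, and adjusted p = 0.031 with an estimated correlation). Harvest hour is not given in the labels, and the fall of GI was not called under spike-in scaling (log2 change -0.01). In the list of other antioxidant enzymes 3 of 4 members fell, the peroxiredoxin AT3G52960 1.81-fold, the plastid glutathione reductase GR 1.38-fold and CCS 1.25-fold. That list passed at the preset correlation (adjusted p = 0.030) but not beyond it (adjusted p = 0.10 with an estimated correlation), and under spike-in scaling GR and CCS were not called (log2 changes -0.23 and -0.08). Of the 8 measured ascorbate genes 3 rose and 3 fell, and the list, with a mean of -0.04, did not pass (adjusted p = 0.97). Fry gave an adjusted p of 0.038 for that list, in the lower direction. The phosphomannomutase PMM rose 1.5-fold and the monodehydroascorbate reductase ATMDAR2 1.46-fold, while the thylakoid ascorbate peroxidase TAPX fell 1.48-fold and VTC4, a galactose-1-phosphate phosphatase of ascorbate synthesis, fell 1.46-fold. In the auxin list IAA29 fell 2.18-fold, HAT2 fell 1.32-fold and GH3.3 rose 1.96-fold, with HAT2 not called under spike-in scaling (log2 change -0.17), and the list did not pass (adjusted p = 0.97). Among the photosynthesis genes SBPASE fell 1.43-fold, PRK 1.16-fold and RCA 1.12-fold, and the list did not pass (adjusted p = 0.28). The calls of PRK and RCA were lost under quantile normalization (log2 changes -0.16 and -0.12), and under spike-in scaling both changes turned above 0 (0.02 and 0.07). PRK was not called without wild type replicate 1 or 2 (adjusted p = 0.0507 and 0.0566), and RCA without any of the 3 wild type arrays or vtc1 replicates 2 and 3 (adjusted p = 0.0525 to 0.0699).

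The other lists gave fewer calls in vtc1. Of 6 measured genes of flavonoid and anthocyanin synthesis, below the anthocyanin list, UGT78D1 rose 1.22-fold. That call was lost without vtc1 replicate 1 or 2 (log2 changes 0.25 and 0.23), and the list did not pass (adjusted p = 0.97). In the jasmonate and ethylene list PDF1.2b, whose probe set can take up related transcripts, rose 1.25-fold. THI2.1 fell at least 1.10-fold to control level (list adjusted p = 0.97). OPCL1 of jasmonate synthesis rose 1.35-fold. Both carbon starvation genes fell, MCCA 1.56-fold and AKINBETA1 1.29-fold, the latter not called under spike-in scaling (log2 change -0.13). In the sugar and starch list APL3 rose 1.78-fold and DPE1 fell 1.25-fold, with DPE1 not called under spike-in scaling (log2 change -0.09), and the list did not pass (adjusted p = 0.97). Of the glucosinolate genes BCAT4 fell 1.19-fold (log2 change -0.02 under spike-in scaling, not called) and UGT74B1 rose 1.13-fold, not called without wild type replicate 1 (0.16) or vtc1 replicates 1 and 2 (0.17 and 0.16). In the expansin and xyloglucan list the members were not called, the list mean was 0.09 (adjusted p = 0.28), and XTH18 and XTH19 lay at control level. AUR1, the only measured cell division gene, had a log2 change of -0.04, not called. Among markers of other tissues, 1 of 3 root genes fell, EXPA7 by 1.26-fold, a call lost without wild type replicate 2 (log2 change -0.28) and under spike-in scaling (-0.10), and the root list did not pass (adjusted p = 0.97).

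Over all probe sets, 8327 (36.6%) were called in vtc1 versus wild type, 4123 higher and 4204 lower, with a median absolute log2 change of 0.35 among the called. At 2-fold or more there were 384 higher and 139 lower, or 665 and 82 under spike-in scaling. Arrays did not overlap for 41.9% of the probe sets, against 5.71% by chance. The share of higher calls was 49.5% as deposited, 36.4% after subtraction of array medians and 89.5% under spike-in scaling, so the balance of directions rests on the scaling.

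**Figure D1:**
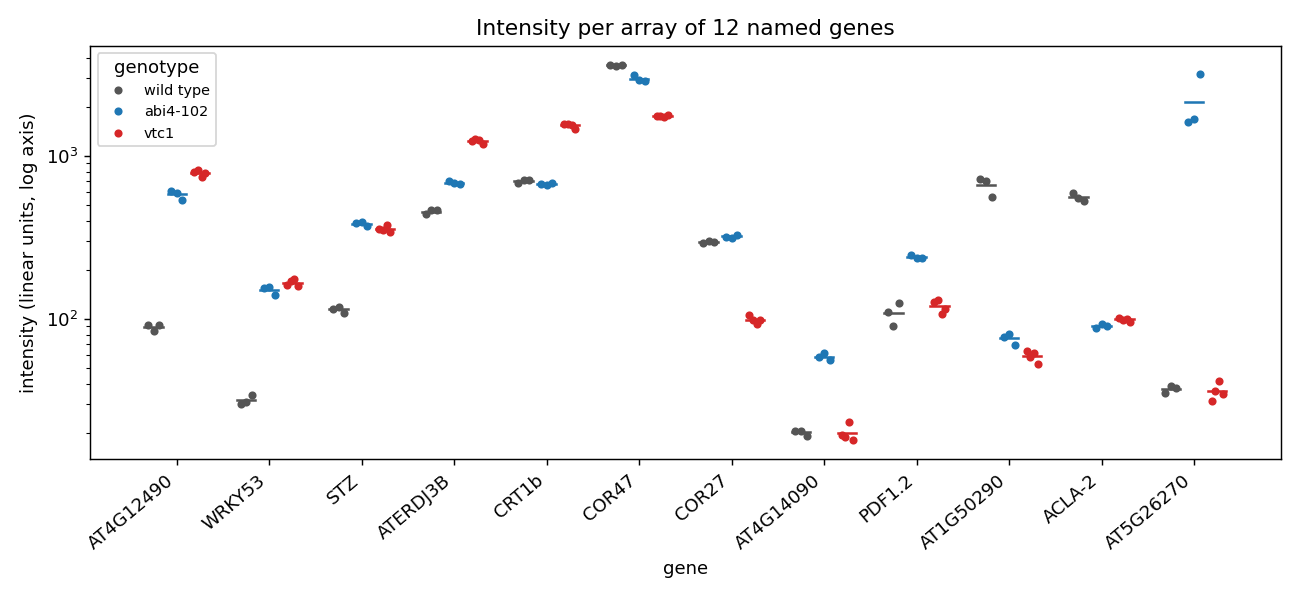
Intensity of 12 named genes on each array, on a log axis, with 1 point per array (wild type n = 3, abi4-102 n = 3, vtc1 n = 4) and a line at each group mean. WRKY53 lies at a mean of 31.6 in wild type, 150 in abi4-102 and 166 in vtc1, while AT5G26270 has a mean of 2144 in abi4-102 and 37.1 in wild type.

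The comparison of abi4-102 with wild type asks the same of the abi4-102 line. The largest increase was in AT5G26270, from 37.1 ± 1.87 (SD, n = 3) to 2144 ± 872 (n = 3), a 53.6-fold rise. QQS, a gene named for its effect on leaf starch, rose 10.1-fold from 46 ± 4.81 to 472 ± 33.6. AT4G12490 rose 6.47-fold, AT5G52390 4.94-fold, AT2G44240 4.66-fold and WRKY53 4.64-fold. AT5G03090, AT3G10930, AT4G12500 and the annotated pseudogene AT4G03530, whose probe set can take up related transcripts, rose from control level by at least 6.20-fold, 4.07-fold, 3.81-fold and 2.81-fold. AT1G50290 was 8.53-fold lower at 75.9 ± 5.87, AT5G15360 6.25-fold, ACLA-2 6.12-fold, AT1G62290 5.51-fold, CSLA01 4.99-fold, AT2G40960 4.96-fold and CYTC6A 4.50-fold. WNK9, AT3G28320 and AT5G50310 fell to control level, by at least 4.29-fold, 5.19-fold and 3.94-fold.

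Genes of flavonoid and anthocyanin synthesis, of which 6 of 18 listed were measured, rose in abi4-102. In that list 5 of 6 members rose over all genes tested and 6 of 6 when adjusted over the list alone. They were led by the glucosyltransferase AT4G14090 (2.82-fold, to 58.6 ± 3.18), UF3GT (1.66-fold) and UGT78D1 (1.51-fold), and by DFR. DFR, dihydroflavonol reductase, rose at least 1.17-fold above control level. The list mean was 0.70 (adjusted p = 0.00030, and adjusted p = 0.049 with an estimated correlation). Of the jasmonate and ethylene defence genes the defensin PDF1.2 rose 2.21-fold and PDF1.2b 1.92-fold, and THI2.1 had a log2 change of -0.26, called. The probe set of PDF1.2b can take up related transcripts, so the 2 defensins of this list may not be separate measurements. That list did not pass (adjusted p = 0.074), although it did without wild type replicate 3 (adjusted p = 0.0484), and THI2.1 was not called under spike-in scaling (log2 change -0.22). All 3 oxidative stress genes rose: STZ 3.34-fold, AT2G21640 1.41-fold, and GSTU25, whose arrays all lay at control level. In the salicylic acid list WRKY53 and GRX480 (2.06-fold) rose and SAG101 and UGT76B1 were not called over all genes. Both lists passed at the preset correlation (adjusted p = 0.0039 each) and missed the threshold otherwise (adjusted p = 0.058 each with an estimated correlation). In the endoplasmic reticulum stress list BZIP60 rose 1.90-fold and ATERDJ3B 1.51-fold and CRT1b was not called (adjusted p = 0.036, and adjusted p = 0.12 with an estimated correlation, or adjusted p = 0.0503 without abi4-102 replicate 3). In the expansin and xyloglucan list 4 of 6 members were called higher, EXPA4 (1.27-fold), EXPA9 (1.23-fold), and XTH19 and XTH16, whose arrays all lay at control level. EXPA9 was not called without wild type replicate 1 or abi4-102 replicate 2 (log2 changes 0.22 and 0.25), nor XTH16 without wild type replicate 2 or abi4-102 replicate 1 or 3 (0.15, 0.18 and 0.19). The list passed only at the preset correlation (adjusted p = 0.047, and adjusted p = 0.12 with an estimated correlation, and not without abi4-102 replicate 3, with a list mean of 0.23).

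Members of the photosynthesis and sugar lists, with 5 of 35 and 4 of 22 listed genes measured, fell in abi4-102. PRK, phosphoribulokinase, fell 1.60-fold from 4146 ± 70.8 to 2606 ± 244, RCA 1.28-fold and SBPASE 1.21-fold, and the light-harvesting genes LHCB4.1 and LHCB4.2 were not called. ATSPS4F, a sucrose phosphate synthase, fell 1.74-fold and the branching enzyme SBE2.2 1.42-fold. Neither the photosynthesis nor the sugar list passed (adjusted p = 0.059 each). Photosynthesis passed without wild type replicate 3 or abi4-102 replicate 1 (adjusted p = 0.0484 and 0.0466), and sugar without wild type replicate 3 or abi4-102 replicate 2 (adjusted p = 0.0456 and 0.0473). SBPASE was not called under spike-in scaling (log2 change -0.25). AT3G52960 fell 1.60-fold and GR 1.53-fold in the list of other antioxidant enzymes (adjusted p = 0.036, and adjusted p = 0.12 with an estimated correlation, or adjusted p = 0.0565 without abi4-102 replicate 1). In the ascorbate list 2 of 8 genes rose and 2 fell: ATMDAR2 rose 1.43-fold and PMM 1.35-fold while VTC4 fell 1.43-fold. The list did not pass (adjusted p = 0.83), although the mixed fry test gave an adjusted p of 6.5e-07. GI fell 1.49-fold and AT4G33980 1.42-fold, and the circadian list did not pass (adjusted p = 0.11). In the abscisic acid list LEA4-5 fell 1.36-fold and COR47 1.21-fold, and the list did not pass (adjusted p = 0.32). COR47 was not called under spike-in scaling (log2 change -0.24). MCCA fell 1.53-fold, EXPA7 of the root markers 1.33-fold and UGT74B1 1.17-fold, while WRKY6 rose 1.85-fold and SAG29 1.24-fold in the senescence list. UGT74B1 was not called under spike-in scaling (log2 change -0.20). AT5G37670 of the heat shock list (log2 change 0.17), JMT of jasmonate synthesis (0.05), AUR1 (0.10) and HAT2 of the auxin list (-0.20) were not called, although HAT2 was under quantile normalization (-0.26) and without abi4-102 replicate 1 (-0.25). The heat shock, auxin and root lists did not pass (adjusted p = 0.76, 0.83 and 0.68). The guard cell marker AT1G22690 rose 1.58-fold and the phloem marker AT5G18600 1.36-fold, whereas in vtc1 they fell by 0.40 and 0.21 on the log2 scale. Under spike-in scaling these changes of vtc1 were -0.17 and 0.02, neither of them called.

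In abi4-102, 7928 probe sets (34.9%) were called, 4283 higher and 3645 lower, with 247 and 76 at 2-fold or more. The share of higher calls was 54.0% as deposited, 48.4% under quantile normalization, where lower calls prevailed, and 62.2% under spike-in scaling, and with a pseudocount of 16 the counts at 2-fold or more were 142 and 50. Arrays did not overlap for 43.5%, against 10% by chance.

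Set against each other, the mutants differed at 8872 probe sets (39.0%), 4054 higher and 4818 lower in vtc1, of which 82 and 100 differed by 2-fold or more. All 6 measured genes of the anthocyanin list were lower in vtc1 than in abi4-102 (list mean -0.72, adjusted p = 0.00057, and adjusted p = 0.045 with an estimated correlation). So were PDF1.2 (2.0-fold) and PDF1.2b (1.53-fold, on a probe set that can take up related transcripts) of the jasmonate and ethylene list (adjusted p = 0.0094, and adjusted p = 0.082 with an estimated correlation). All 3 endoplasmic reticulum stress genes were higher in vtc1, CRT1b 2.29-fold, ATERDJ3B 1.80-fold and BZIP60 1.13-fold (adjusted p = 0.00072, and adjusted p = 0.045 with an estimated correlation). BZIP60 was not called when abi4-102 replicate 2 or 3 or vtc1 replicate 2, 3 or 4 was left out (log2 changes 0.14 to 0.18). COR27 was 3.21-fold lower in vtc1. In the abscisic acid list COR47 was 1.70-fold and COR15A 1.58-fold lower (adjusted p = 0.031, and adjusted p = 0.13 with an estimated correlation). In the sugar and starch list ATSPS4F was 1.70-fold and APL3 1.61-fold higher (adjusted p = 0.029, and adjusted p = 0.18 with an estimated correlation), and SAG101 was 1.64-fold higher. The other lists tested did not pass between the mutants (adjusted p = 0.091 to 0.91), although the circadian and heat shock lists did under spike-in scaling (list means -0.64 and 0.60). AT5G26270 was 55.6-fold lower in vtc1, AT2G15560 7.15-fold, and AT5G03090, AT4G03530 and the annotated pseudogene AT5G26020 at least 6.67-fold, 3.02-fold and 3.49-fold. AT5G50310 was at least 4.2-fold higher in vtc1, AT2G40960 3.84-fold, LUP5 3.77-fold, AT3G28510 3.49-fold and AT1G35710 3.43-fold. The share of higher calls was 45.7% as deposited and 86.8% under spike-in scaling, where 239 were higher and 43 lower by 2-fold or more, so the balance of directions rested on the scaling here too. At 2-fold or more it was near even under quantile normalization (96 and 95) and with a pseudocount of 16 (51 and 50).

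Both mutants shared many changes against wild type. AT4G12490, AT3G10930, WRKY53, AT2G44240 and AT3G16530 rose in both, AT3G16530 by 3.66-fold in each, and AT1G50290, AT5G15360, AT3G28320, WNK9 and ACLA-2 fell in both. Of the probe sets called in both, 2212 were higher in both, 1703 lower in both and 661 went in opposite directions. Independent lists of these sizes would share 776 and 674. Unchanged mutants simulated against the same controls shared at most 1, but with no changed probe set they yield few calls by construction. Neither number measures how far the shared wild-type arrays raise the overlap of real changes. At 2-fold or more in both, 151 were higher and 52 lower. The log2 changes correlated at 0.61 across probe sets, which are not independent, against 0.53 in simulated unchanged mutants, and their covariance was 0.068 against 0.0032. The share of probe sets with the same sign in both mutants showed no excess, at 66.1% against 67.9% in simulated unchanged mutants. The actin 3' minus 5' difference was also lower in both mutants than in wild type.

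**Figure D2:**
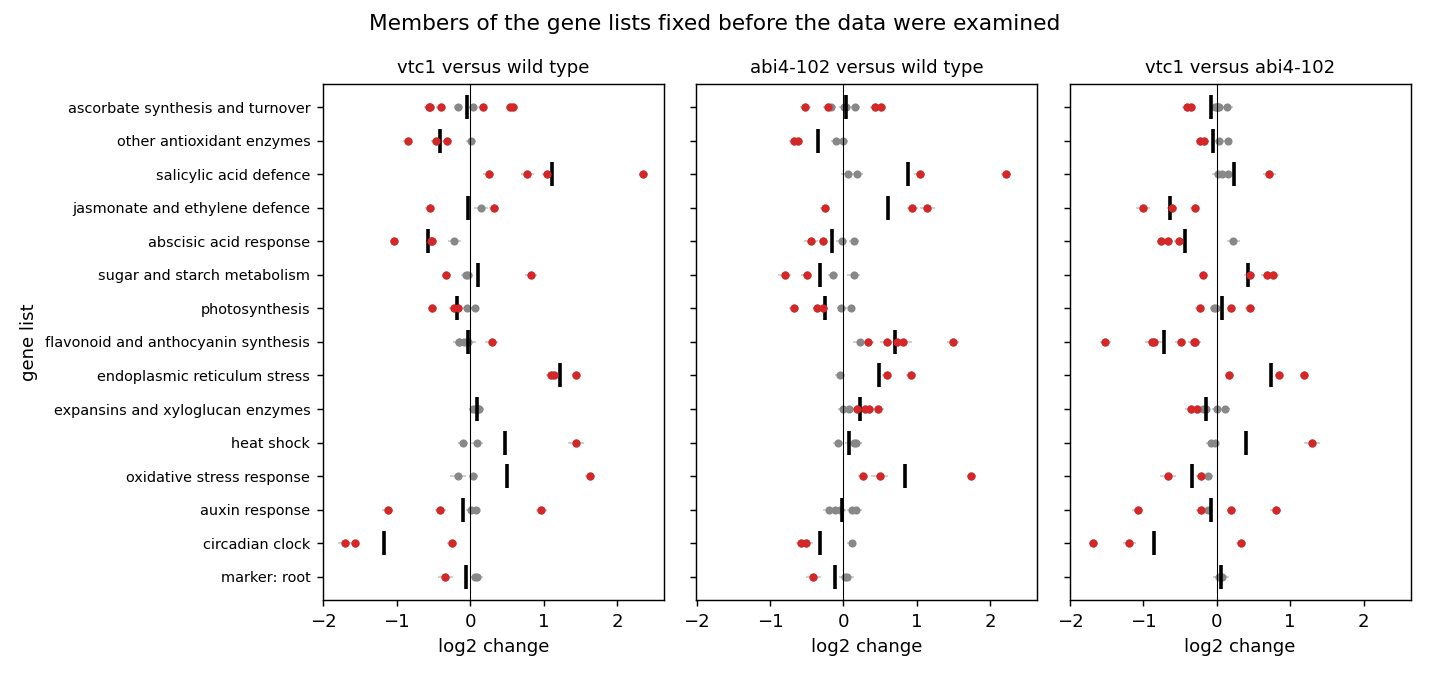
Log2 change of each measured member of the 15 gene lists with at least 3 measured members, in 3 panels by comparison; red points were called, grey points were not, horizontal bars are SE and the black tick is the list mean. The endoplasmic reticulum stress list has a mean of 1.23 in vtc1 versus wild type, and the anthocyanin list a mean of 0.70 in abi4-102 versus wild type.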

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

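All tests on the patterns of this part were chosen after the changes they bear on were seen, except the splits of the arrays, the mitochondrial test and the search for neighbouring genes.

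Among 96 named probe sets, 3 had a vtc1 array apart from the others, where chance gives about 4.8. For WNK9 replicate 2 stood at an intensity of 13.9 against 12.2 to 12.3, a gap of 0.99 of the range. For UGT76B1 replicate 2 was at 25.5 against 26.2 (gap 0.96), and for MSRB9 replicate 1 was at 293 against 257 to 261 (gap 0.89). Control probe sets outside the comparisons also differed: on the log2 scale the hybridization spike-in controls were at -0.24 in vtc1 relative to wild type, and the actin, GAPDH and ubiquitin controls at 0.39.

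A chance assignment of arrays to groups as the source of the counts is argued against in 2 comparisons. In vtc1 versus wild type 1 of 35 splits of the arrays, the real one, called 8327 probe sets, and the highest other split called 0. In vtc1 versus abi4-102 it was again 1 of 35, with 8872 against 0. In abi4-102 versus wild type there are 10 splits, too few for a share under 0.05. The real one, 1 of the 10, called 7928 and the highest other 0.

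Plastid-encoded transcripts were lower in vtc1: 54 of 69 measured genes fell by limma, with a mean log2 change of -0.51 (adjusted p = 0.12 for the group with an estimated correlation), and in abi4-102 29 fell and 7 rose (mean -0.17, adjusted p = 0.35), with vtc1 below abi4-102 at 50 of 69 (mean -0.35, adjusted p = 0.15), or at 22 with 2 higher and overlapping arrays under spike-in scaling (mean -0.14). Scaling of the arrays as the whole cause of the change in vtc1 is argued against, since the mean nearest to 0 over 3 other scalings, that of spike-in scaling, was still -0.28 ± 0.07 (SE over arrays), with 37 lower and 5 higher. A lower yield of transcripts without a poly(A) tail would lower mitochondria-encoded genes too. Their mean change was -0.12 ± 0.05 (SE over 16 genes), past the bound set beforehand against that explanation. That bound was wrong, because dim genes pull the mean to 0: the 7 genes above the control level, chosen after that value was seen, averaged -0.23 ± 0.10 with 4 lower, so low yield and an effect of the genotype cannot be told apart.

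Log2 changes followed gene length across 13333 genes, with Spearman's rho of -0.22 in abi4-102 versus wild type, 0.15 in vtc1 versus wild type and 0.34 between the mutants. A gene length trend as the whole cause of the calls against wild type is argued against. After it was taken out, 85.5% of the called genes kept call and direction in abi4-102 and 90.4% in vtc1. Between the mutants, where the trend was strongest, 77% kept them. That falls short of the bound chosen for abi4-102, so the calls between the mutants are left undecided. RNA integrity stays open as a source of the trend: the 3' minus 5' log2 difference of the actin control was 0.084 higher in vtc1 than in abi4-102 with overlapping arrays, and that of GAPDH went the other way, at 0.27 and 0.29. Against wild type the actin difference was lower in both mutants with no overlap, at 1.69 to 2.1 in wild type, 1.36 to 1.56 in abi4-102 and 1.49 to 1.67 in vtc1, while the arrays overlapped for GAPDH. For actin both mutants thus lay on the same side of wild type, while their length trends ran in opposite directions (rho -0.22 and 0.15). A difference in integrity as actin shows it would therefore not account for both trends. For either trend alone this pair of control genes does not decide, so integrity and genotype cannot be told apart there.

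Of the genes lower by 2-fold or more in both mutants, 32 had a place in the gene table. A linked segment of another background around the targeted loci, acting on the genes it holds, is argued against as the cause of this set, since 31 of the 32 lay on other chromosomes than VTC1 and ABI4 and 0 lay within 100 genes of either. Clusters of neighbouring genes are argued against likewise, since 0 of the 32 had another within 10 genes, although random sets averaged only 0.74 and genes without a probe set of their own were not searched. Differences between the wild-type plants and both mutant lines elsewhere in the genome, or in RNA quality, stay open beside a shared response and were not tested for this set.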

How the results depend on the processing

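Spike-in scaling, the omission of a pseudocount, the pseudocount of 16 for results other than the vtc1 count, and the alternatives for gene groups by symbol were chosen after the data were seen. At 2-fold or more the counts fell to 523 in vtc1, 323 in abi4-102, 182 between the mutants and 203 shared, because the threshold is stricter. Without 1 array they ranged over 7267 to 8057, 7060 to 7379, 7800 to 8388 and 3456 to 3807. The spike-in counts were 11527, 5971, 9938 and 3542. For 203 results on named genes 3214 of 3354 alternatives gave the same direction and side of the threshold, 99 lost the call, 15 gained one and 26 reversed, 5 of these for called genes. For 45 list results it was 732 of 783, with 22 lost, 13 gained and 16 reversed. For 29 group results it was 444 of 510, with 66 lost. Over all 3 genotypes the same-numbered replicates did not pair clearly: their 9 correlations were -0.055 to 0.10 and 8 of 18 matched best with their own number. Between wild type and vtc1, however, the same-numbered correlations were 0.087, 0.044 and 0.10, each the best vtc1 match of its wild-type array. Arrays of different numbers reached at most 0.075 over all genotypes. A weak pairing of these 2 groups stays open, and with the replicate block 7414 probe sets were called in vtc1. Probe sets near the control level limit the dim genes.

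Reversed log2 changes were as follows, and the cause was not tested. Under quantile normalization AT3G16530 between the mutants was at 0.046 and the ascorbate list in abi4-102 at -0.029. With array weights AT3G16530 was at 0.015, and with a pseudocount of 16 the jasmonate and ethylene list in vtc1 was at 0.050. Spike-in scaling gave most of the others. Between the mutants it put AT2G44240 at 0.13, AT3G16530 at 0.20, AT5G15360 at 0.019, AT3G28320 at 0.12, AT3G52960 at 0.028, DPE1 at 0.022 and AUR1 at 0.063. Against wild type it put PRK in vtc1 at 0.018, RCA at 0.074, AUR1 at 0.20 and AT5G18600 at 0.023, and OPCL1 in abi4-102 at 0.018. Lists in vtc1 came to 0.19 for ascorbate, 0.21 for jasmonate and ethylene, 0.064 for photosynthesis, 0.21 for anthocyanin, 0.14 for auxin and 0.18 for root markers, and the auxin list in abi4-102 to 0.018. Between the mutants lists came to 0.13 for ascorbate, 0.15 for other antioxidants, 0.062 for expansins and 0.12 for auxin.

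Leaving out 1 array at a time also reversed results near 0. In vtc1 AUR1 ranged from -0.11 to 0.0027, the jasmonate and ethylene list from -0.058 to 0.0091 and the anthocyanin list from -0.046 to 0.0058. In abi4-102 AUR1 ranged from -0.015 to 0.17, JMT from -0.040 to 0.14, OPCL1 from -0.085 to 0.039 and the auxin list from -0.036 to 0.016. Between the mutants AT3G16530 ranged from -0.031 to 0.024, AT3G28320 from -0.15 to 0.0071, EXPA7 from -0.063 to 0.15 and the log2 change of PYK10 vtc1 versus abi4-102 from -0.00235 to 0.10.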

Other observations

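The gene groups below were formed after the data were seen, and the tests on them were chosen then; with an estimated correlation none of the 29 group calls passed. Of 7 calmodulin-like CML genes 5 rose in vtc1, CML37 with a log2 change of 1.33 and CML38 with 0.82, and 6 rose in abi4-102, with CML38 at 1.45 and CML41 at 1.13 (camera adjusted p = 0.0010 and 0.0024, and adjusted p = 0.22 and 0.24 with an estimated correlation). Of 7 glutamate receptor-like GLR genes 4 rose in vtc1, with GLR2.8 at 1.52 and GLR2.7 at 1.18. GLR genes were higher in vtc1 than in abi4-102 at 5 of 7 (mean 0.47, adjusted p = 0.058 with an estimated correlation). WRKY47 changed by 1.53 in vtc1 and 1.29 in abi4-102.

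In abi4-102 all 6 LSM genes, which encode small RNA-binding proteins, were higher than in wild type with a mean of 0.40, while 7 of 12 UBP genes, which encode ubiquitin proteases, were lower, with a mean of -0.22 (adjusted p = 0.24 each with an estimated correlation). Between the mutants all 6 LSM genes were lower in vtc1, and 7 of 12 UBP genes and 8 of 9 genes with SEC symbols were higher. These changes ran the way of the gene length trend, with a median gene length of 1418 bases for LSM, 3951 for UBP and 6063 for SEC against 2103 for all genes. With the trend taken out, the mean in abi4-102 was 0.35 for LSM (5 of 6 higher) and -0.13 for UBP (5 of 12 lower), and between the mutants it was -0.29 for LSM, 0.23 for UBP and 0.27 for SEC. Under spike-in scaling the UBP call in abi4-102 was lost (mean -0.19). The CML calls in both mutants were lost when dim probe sets were left out (means 0.35 and 0.62).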
